A study of Mus musculus with 20 samples.

How the data were processed

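RNA was sequenced from 20 libraries of mouse bone-marrow cells sorted as LT-HSC, MPP2 or MPP3 from Hopx wild-type and Hopx knockout animals, per the labels. The authors aligned reads with TopHat2 2.1.1 to GRCm38, counted them per Ensembl gene with HTSeq 0.11.2 and scaled them with DESeq (no version given), per the submitters' processing notes. The deposited values are a normalized signal: each count was divided by 1 size factor per library. The annotation release, the strand setting of the counting and any filter are not given in the sources used here. Every value was a whole multiple of its library's smallest value within a tolerance of 1e-06, so whole reads were recovered from the deposited values. In WT MPP3 replicate 1 and WT MPP2 replicate 2 a single read has a value of 1.00868 and 1.00071, too near 1 for an automatic check of whole reads to judge, and edgeR was therefore also run on the other 18 libraries. The deposited size factors differed from median-ratio factors recomputed here by a ratio of 0.999887 to 1.00015.

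Reads assigned to genes numbered 12094117 to 14640726 per library in KO LT-HSC, 13933069 to 15189909 in KO MPP2 and 12565013 to 14658320 in KO MPP3. They numbered 12475841 to 14647699 in WT LT-HSC, 13035794 to 15153309 in WT MPP2 and 11163345 to 14711129 in WT MPP3. The file's 5 HTSeq summary entries were left out of all totals and tests. Of all entries per library, reads outside genes made up 22.9 to 26.7%, ambiguous reads 0.274 to 0.341%, alignments that were not unique 52.6 to 57.8% and reads in genes 18.5 to 21.4%. Of 45706 gene identifiers, 45143 matched a symbol in GENCODE M21 (GRCm38) and 563 did not. Groups and the knockout state were taken from the labels, replicate numbers follow accession order only, and sex was read from Xist and Y-linked transcripts. Every pair of libraries within a group differed by far more than counting error, with a chi-square per gene of at least 32.7 over 24 pairs and a Pearson correlation across genes, which are not independent replicates, of 0.831 to 0.932.

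Counts with an edgeR quasi-likelihood test had been set as the main analysis before the data were examined. Since the values were deposited as scaled signal, the main test was instead limma 3.58.1 in R 4.3.3, with an intensity trend and robust variances, on log2(value + 1), with the deposited scaling. Group means of 6 groups were fitted over 20 libraries, for 17160 genes kept by edgeR's expression filter. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The added 1 shrinks the fold changes of genes with few reads. Each fold change is a difference of mean log2 values. Where libraries of a group differ widely or lie at 0, it can exceed the ratio of the group means printed beside it. Procr and Flt3 in WT MPP2 are such cases. The comparisons were KO with WT in each population, their average over the populations, a test of whether the KO effect differed between populations, and the pairwise differences of the WT populations. Gene lists, 35 in number and written before the data were examined, held 607 genes of which 552 were measured. They were tested in 7 comparisons with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 35 lists of each comparison, and again with an estimated correlation, and with fry. A list called by camera differs from the other genes as a set, and none of its single genes need pass.

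The genes named were set by a rule written before the data were examined. Hopx came first, then in each comparison the 12 highest and 12 lowest fold changes among called genes with a mean log2 CPM of at least 3 and with all libraries of one group beyond all of the other. Where fewer than 10 genes qualified, each qualifying gene was named, with the 5 genes of smallest p in each direction that did not pass. For the average and the test of the difference, up to 8 passing genes were named. Lists were represented by up to 4 members of smallest p. A fixed set of lineage genes was looked up in each WT comparison: Procr, Mpo, Elane, Pf4, Itga2b, Gata1, Flt3, Dntt, Mki67, Cd34, Slamf1 and Cd48. Library-by-library values quoted for other genes, and Sva and Eps8l1 in single populations, were chosen after their values were seen. A few genes that the rule selects are not reported here.

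A fold against a group with 0 reads was computed against a floor of 3 counts over the group and is a lower bound. Ratios with 1 read carry a 95% counting interval, and floors and intervals cover counting error only. With members at such bounds, the medians of 6 of 55 called lists moved, by at most 0.44 on the log2 scale, with 0 sign changes.

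Both gene tests were tested on simulated counts with 200 changed genes among 17160. Changed genes had a mean log2 CPM of at least 3, and list genes a higher level. Genes were drawn independently of one another, with no effect of block, sex or animal. The shares therefore do not cover genes with fewer reads. False calls from correlated genes or libraries were not tested, so real power and error control may be worse. In the simulated KO MPP2 comparison limma recovered 12% of genes changed 2-fold, 68% at 4-fold, 88% at 8-fold and 96% at 16-fold, with 4 false calls. For KO LT-HSC the shares were 24, 64, 96 and 98% with 8 false calls, and for KO MPP3 18, 76, 88 and 94% with 10. Camera called the raised list in the simulated KO LT-HSC comparison and 1 of 34 unchanged lists. The alternatives tried were no expression filter, DESeq2 1.42.0, edgeR 4.0.16, voom with quality weights, other scalings and pseudocounts, fits of the compared groups alone, covariates for library-number block and for sex, and leaving out each library in turn or the 3 libraries numbered 52 to 54. No sample column was left out.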

Results

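Gene expression was measured by RNA sequencing in 20 libraries of sorted mouse bone-marrow cells, 11 from animals with an intact Hopx gene (wild type, WT) and 9 from Hopx knockouts (KO). The animals were 8 weeks old and on the C57BL/6 background. The sorted cell populations were: long-term haematopoietic stem cells (LT-HSC), the cells that sustain blood formation, and the multipotent progenitor types MPP2 and MPP3. As background, MPP2 are known to lean toward platelet and red-cell output, and MPP3 toward granulocytes and macrophages. There were 3 KO libraries of each population, and 4 WT LT-HSC, 3 WT MPP2 and 4 WT MPP3 libraries. Reads assigned to genes ran from 11163345 to 15189909 per library, and between 14931 genes (KO MPP2 replicate 3) and 20831 genes (WT MPP3 replicate 2) had at least 1 read. By Xist and Y-linked transcripts, each KO group held 2 female libraries and 1 male library. The same transcripts gave 1 female and 3 male libraries in WT LT-HSC, 1 and 2 in WT MPP2, and 1 and 3 in WT MPP3. The labels name no animal, so every p-value measures only the spread between these libraries, and libraries of different populations may come from the same animal.

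Hopx, which encodes a small homeodomain protein that does not bind DNA, was read in 10 of 11 WT libraries and in 0 of 9 KO libraries. The gene lies on chromosome 5 at 77086988 to 77115121 on the minus strand (GRCm38) and is protein-coding. Its mean normalized count was 31.6 ± 24.3 (SD, n = 4) in WT LT-HSC, 37.5 ± 25.2 (n = 3) in WT MPP2 and 26.98 ± 12.98 (n = 4) in WT MPP3. The exception was the library labelled WT LT-HSC replicate 4, where Hopx was 0 while the other WT LT-HSC libraries ran from 30.2 to 58.9. With 349 Hopx reads in WT and 0 in KO, and a floor of 3 counts over the group, Hopx was at least 98.2-fold lower in KO over all populations. The same bound was at least 32.5-fold in LT-HSC, 40.9-fold in MPP2 and 26.9-fold in MPP3, and these bounds cover counting error only. On average over the populations Hopx passed the limma test (log2 fold change -4.56, SE 0.64, adjusted p = 0.0115). Within single populations it did not pass on all libraries, with -4.03 in LT-HSC (limma adjusted p = 1), -4.97 in MPP2 (limma adjusted p = 0.257) and -4.67 in MPP3 (limma adjusted p = 1). The exceptions were LT-HSC and MPP3 without the library labelled WT LT-HSC replicate 4 (limma adjusted p = 0.0274 and 0.0464) and MPP2 with DESeq2 (DESeq2 adjusted p = 0.0206). The average call was lost with voom weights, the library-number covariate, edgeR on 20 or 18 libraries, a pseudocount of 16 or without the libraries numbered 52 to 54. Over 32 settings the limma, edgeR or DESeq2 adjusted p ran from 3.71e-08 to 0.718.

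**Figure D1:**
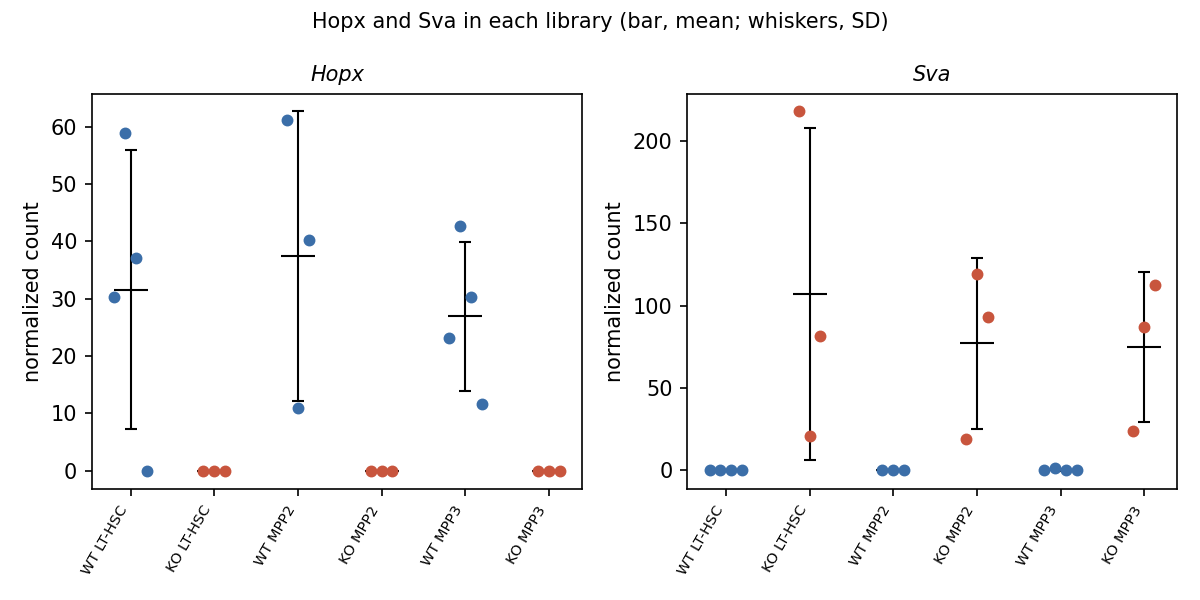
Normalized counts of Hopx and Sva (y axes) in each of 20 libraries, by group (x axis); points are libraries (blue, WT; red, KO), bars the mean and whiskers the SD. Hopx is 0 in 9 KO libraries and in the library labelled WT LT-HSC replicate 4, and Sva is between 19.1 and 217.8 in the KO libraries and at most 1.26 in WT.

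The difference between the progenitors and the stem cells was taken first, in wild type. MPP3 carried transcripts of granule proteins and of early lymphoid genes that were near 0 in LT-HSC. Mpo, the peroxidase of neutrophil granules, was 56780 ± 48331 normalized counts in WT MPP3 (n = 4) against 43.4 ± 67.8 in WT LT-HSC (n = 4), a log2 fold change of 11.75 (SE 1.91, limma adjusted p = 0.0013). Ctsg, a granule protease, had 0 reads in the 4 WT LT-HSC libraries and 4493 ± 3669 in WT MPP3, at least 6543-fold higher against a floor of 3 counts over the group (limma adjusted p = 0.000798). Dntt, the polymerase that adds nucleotides to antigen-receptor joints, was 9578 ± 5049 against 5.84 ± 11.7 (log2 11.95, SE 2.097, limma adjusted p = 0.00237). Platelet and stem-cell genes fell. Cavin2, a coat protein of caveolae, went from 2372 ± 1323 to 4.96 ± 9.92 (log2 -9.90, SE 0.87, limma adjusted p = 3.85e-06). Vwf, the platelet adhesion factor, fell from 1445 ± 565 to 9.29 ± 8.64, and Slamf1, the gene of the sorting antigen CD150, fell from 987 ± 171 to 12.96 ± 10.04. Among 17160 genes tested, limma called 681, of which 257 were higher and 424 lower in MPP3.

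The 12 genes with the largest rises under the naming rule further held Ighm, the constant part of the IgM heavy chain (log2 10.24), the myeloid lectin receptor Clec12a (8.74) and the flippase gene Atp8b4 (8.49). They also held BC035044 (8.37), the monocyte antigen gene Ly6c2 (8.11), the chemokine gene Ccl9 (8.04), Tespa1, a T-cell receptor signalling gene (7.99), and the calponin Cnn3 (7.09). Gm11505 (10.94) is annotated antisense to Mpo and overlaps it. The strand setting of the counting is not given in the sources used here, so its reads cannot be separated from those of Mpo. The 12 largest falls also held the platelet genes Gp1bb (-7.72), Pf4 (-6.08) and Treml1 (-6.07), the transglutaminase Tgm2 (-6.97) and the endocytic gene Ehd3 (-6.64). The proteoglycan Sdc2 (-6.51), the stress gene Nupr1 (-6.22), the growth suppressor Ndn (-6.04) and Socs2, an inhibitor of cytokine signalling (-5.77), completed them. In each of these 24 genes all libraries of one population lay beyond all libraries of the other, and their largest limma adjusted p was 0.0213 (Ly6c2). Flt3, the receptor of early lymphoid and dendritic progenitors, was higher in MPP3 (log2 4.44, SE 0.83, limma adjusted p = 0.00378). So were Cd48 (log2 5.54, SE 0.95, limma adjusted p = 0.00207) and Cd34 (log2 2.32, SE 0.53, limma adjusted p = 0.0161), genes of antigens commonly used in sorting. Elane, neutrophil elastase, was 4402 ± 5072 in WT MPP3 and did not pass (log2 6.50, SE 3.01, limma adjusted p = 0.338). It was 2.51 in WT MPP3 replicate 2 and 51.7 in WT MPP3 replicate 3. Gata1 (-4.45, limma adjusted p = 0.121), Itga2b (-2.44, limma adjusted p = 0.0575), Procr (-2.37, limma adjusted p = 0.414) and Mki67 (0.28, limma adjusted p = 0.754) did not pass either.

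As groups, 5 gene lists were called between WT MPP3 and WT LT-HSC with either correlation setting of camera. HSC markers fell in 12 of 20 measured genes, or 14 adjusted over the list alone (camera adjusted p = 8.82e-21). Among them was Esam, an adhesion molecule of stem cells (-3.24). Megakaryocyte and platelet genes fell in 10 of 20, or 16 adjusted over the list alone (camera adjusted p = 8.82e-21), with the platelet glycoprotein Gp9 at -3.93. Myeloid genes rose in 11 of 22, or 16 adjusted over the list alone (camera adjusted p = 6.47e-18), with Cebpa, the driver of granulocyte fate, at 4.42. Lymphoid priming genes rose in 11 of 18, or 14 adjusted over the list alone (camera adjusted p = 8.36e-17), with the chemokine receptor Ccr7 at 5.83. The recombinase gene Rag2 had 0 reads in WT LT-HSC and was at least 573-fold higher. Genes of the Hox cluster and its cofactors fell in 3 of 15, or 6 adjusted over the list alone (camera adjusted p = 5.55e-06), with Meis1 at -1.15 and Hoxb5 at -5.31. Dendritic cell genes were called higher with 2 of 10 passing, or 4 adjusted over the list alone (camera adjusted p = 5.55e-06). That call was lost with an estimated correlation (adjusted p = 0.0528). DNA replication genes were called higher with 0 of 21 passing and 0 adjusted over the list alone (camera adjusted p = 7.67e-05). Nuclear oxidative phosphorylation genes were called higher with 1 of 25 passing, Ndufa4 at 0.76, or 2 adjusted over the list alone (camera adjusted p = 0.000906). Both calls were lost with an estimated correlation (adjusted p = 0.385 and 0.436). S100a8, a gene of mature neutrophils, was 10521 in WT MPP3 replicate 2, 9036 in WT MPP3 replicate 3 and 6728 in WT LT-HSC replicate 2. The WT LT-HSC group includes the library labelled WT LT-HSC replicate 4, without which limma called 444 genes. EdgeR called 429 genes, or 242 on 18 libraries, and voom called 1608. With voom, Mpo, Ctsg, Gm11505, Ighm, Ly6c2, Gp1bb and Pf4 lost their calls. Ighm lost its call with edgeR as well, and Ly6c2 in 5 fits without a single library.

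**Figure D2:**
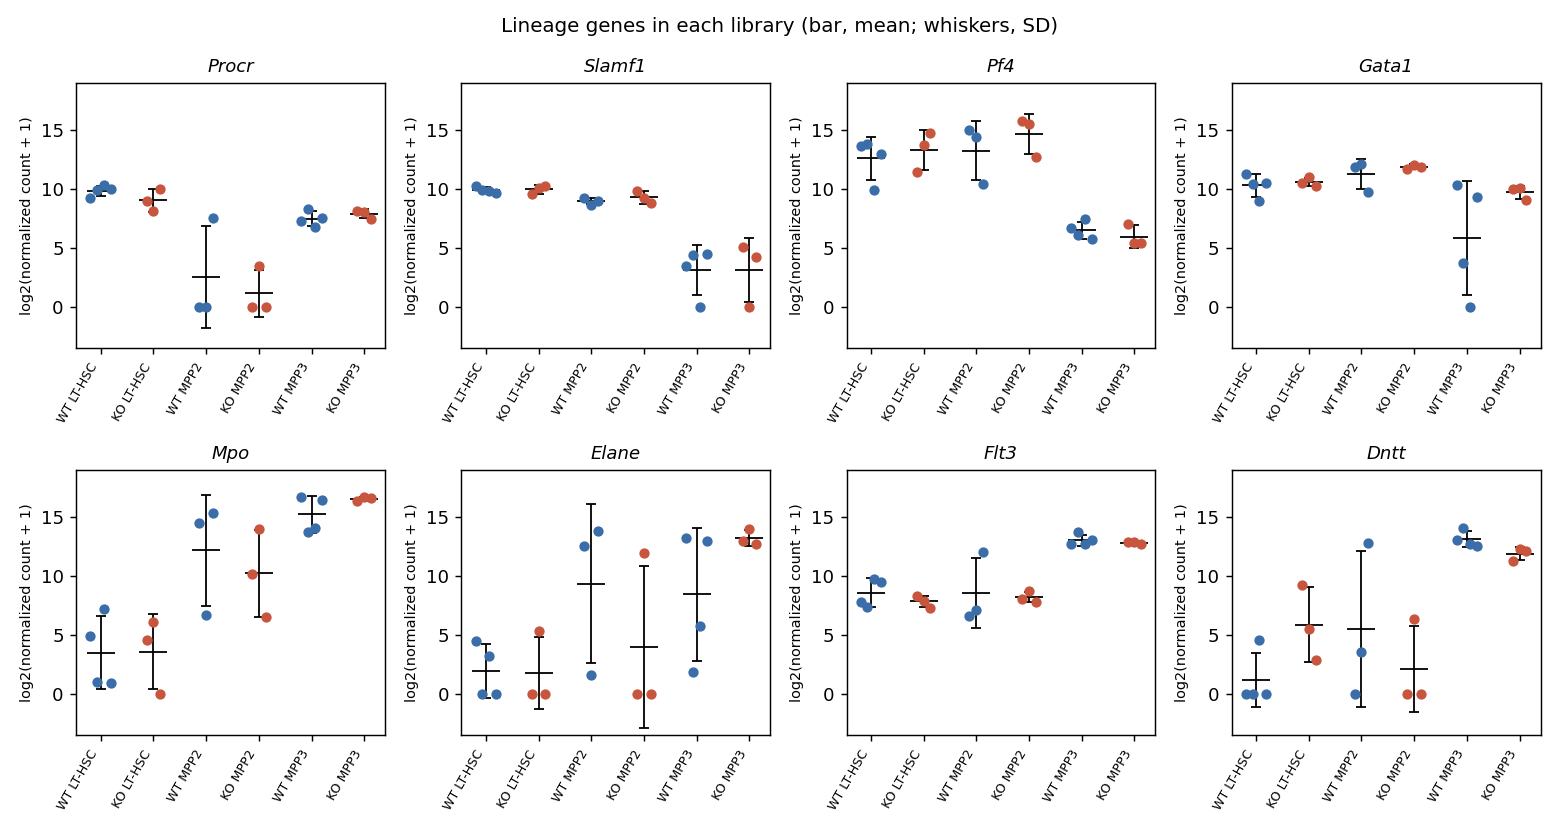
Log2(normalized count + 1) of 8 lineage genes (y axes) in each library, by group (x axis); points are libraries (blue, WT; red, KO), bars the mean and whiskers the SD. Slamf1 and Pf4 are lower, and Mpo, Flt3 and Dntt higher, in WT MPP3 than in WT LT-HSC, while Gata1 and Elane spread widely among the 4 WT MPP3 libraries.

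Compared with WT LT-HSC, WT MPP2 had less of several stem-cell transcripts and more of some genes of granulocyte precursors. Procr, the protein C receptor that marks stem cells, was 60.6 ± 105 normalized counts in WT MPP2 (n = 3) against 951 ± 272 in WT LT-HSC (n = 4), a log2 fold change of -7.34 (SE 1.32, limma adjusted p = 0.0137). Cdkn1c, an inhibitor of cyclin-dependent kinases active in resting stem cells, fell from 529 ± 154 to 58.1 ± 2.15 (log2 -3.12, SE 0.64, limma adjusted p = 0.028). Mllt3, a regulator of stem-cell maintenance, fell from 2084 ± 763 to 374 ± 172 (log2 -2.54, SE 0.45, limma adjusted p = 0.0131). Ms4a3, a gene of granulocyte and monocyte precursors, rose from 41.9 ± 18.9 to 1546 ± 1174 (log2 4.91, SE 0.99, limma adjusted p = 0.0256). Ctsg had 0 reads in WT LT-HSC and was at least 1975-fold higher (limma adjusted p = 0.0425). That call was lost in 22 of 33 settings, among them edgeR, voom, the library-number covariate and 14 fits without a single library. Limma called 143 genes, 48 higher and 95 lower in MPP2.

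The largest falls under the naming rule also held Slfn2, a gene of the quiescence-linked Schlafen family (-4.84), the cytokine gene Ltb (-3.41), the blood-group gene Art4 (-3.32) and Npdc1 (-3.30). The lysosomal protease Ctsf (-2.91), the cytokine-signal inhibitor Cish (-2.51), Eya2 (-2.19), Nfkbiz, a nuclear regulator of NF-kB (-2.17), and Esam (-2.17) completed them. The largest rises held Atp8b4 (6.98), the protease inhibitor Cst7 (5.04), Ubash3a (4.04), Tyrobp, a signalling adaptor of myeloid receptors (4.002), and Plac8 (2.83). They also held the lectin receptor Clec4d (2.72), Tent5a (2.51), the galectin Lgals1 (2.27) and Knl1, a scaffold of the kinetochore (2.06). Gm6030 (1.88) is annotated as a processed pseudogene and may share reads with its parent gene. All WT MPP2 libraries lay beyond all WT LT-HSC libraries for each of these 24 genes, whose largest limma adjusted p was 0.0497 (Atp8b4). The call of Atp8b4 was lost in 24 of 33 settings, that of Lgals1 in 18 and that of Nfkbiz in 16, and 18 of the 24 genes lost theirs with edgeR. Cd48 (log2 4.30, limma adjusted p = 0.056), Mki67, a gene of dividing cells (1.12, limma adjusted p = 0.0657), and Mpo (8.69, limma adjusted p = 0.0547) did not pass. Pf4 (0.67, limma adjusted p = 0.897) and Gata1 (0.97, limma adjusted p = 0.898), genes of the platelet and red-cell lineages, did not pass either. Neither did Dntt (4.32, limma adjusted p = 0.475) or Elane (7.41, limma adjusted p = 0.357).

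Of 16 gene lists called by camera between WT MPP2 and WT LT-HSC, 7 were also called with an estimated correlation. HSC markers fell in 4 of 20 genes, or 13 adjusted over the list alone (camera adjusted p = 2.64e-14). Hox cluster genes and cofactors were called lower, with Hoxb6 (-5.57) passing among 15, or 6 adjusted over the list alone (camera adjusted p = 3.34e-08). Cell cycle inhibitors were called lower, with Cdkn1c passing among 19, or 4 adjusted over the list alone (camera adjusted p = 0.00167). DNA replication genes were called higher, with Tyms, the thymidylate synthase, passing among 21 (0.97), or 12 adjusted over the list alone (camera adjusted p = 8.74e-15). Nuclear oxidative phosphorylation genes were called higher, with Cox5a passing among 25 (0.73), or 7 adjusted over the list alone (camera adjusted p = 2.66e-12). Genes of mast cells, basophils and eosinophils were called higher with 0 of 9 passing, or 5 adjusted over the list alone (camera adjusted p = 1.79e-05), and the mast-cell protease Cpa3 was at 3.33. Monocyte and macrophage genes were called higher with 0 of 12 passing, or 1 adjusted over the list alone, Ly86 at 6.41 (camera adjusted p = 0.00275), a call lost without the libraries numbered 52 to 54.

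The other 9 list calls between WT MPP2 and WT LT-HSC were lost with an estimated correlation. Myeloid genes were called higher with 3 of 22 passing, or 9 adjusted over the list alone (camera adjusted p = 3.34e-08, and adjusted p = 0.0817 with an estimated correlation). Mitosis genes, among them the topoisomerase gene Top2a (1.27), were called higher with 0 of 22 passing, or 11 adjusted over the list alone (camera adjusted p = 5.47e-15, estimated-correlation p = 0.102). Erythroid genes were called higher with 0 of 20 passing and 0 adjusted over the list alone (camera adjusted p = 0.00689, estimated-correlation p = 0.473). Histone genes were called higher with 0 of 17 passing, or 9 higher and 1 lower (Hist1h2bc) adjusted over the list alone (camera adjusted p = 3.34e-08, estimated-correlation p = 0.0817). Immediate early genes, among them Zfp36 (-1.90), were called lower with 0 of 18 passing, or 8 adjusted over the list alone (camera adjusted p = 3.7e-07, estimated-correlation p = 0.183). TNF and NF-kB response genes were called lower with Nfkbiz passing among 18, and 1 adjusted over the list alone (camera adjusted p = 0.0251, estimated-correlation p = 0.0817). Interferon response genes were called lower with 0 of 22 passing, or 1 adjusted over the list alone, Ifitm3 at -0.97 (camera adjusted p = 0.00167, estimated-correlation p = 0.473). The Wnt pathway was called lower with Sfrp1 passing among 19, and 1 adjusted over the list alone (camera adjusted p = 0.0347, estimated-correlation p = 0.0817). Sfrp1, a secreted Wnt antagonist, had 0 reads in WT MPP2 and was at least 108-fold lower. The BMP and TGF-beta pathway was called lower with 0 of 21 passing, or 1 adjusted over the list alone, Eng at -1.03 (camera adjusted p = 0.0251, estimated-correlation p = 0.183).

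WT MPP2 replicate 3 stood apart from the other WT MPP2 libraries. Flt3 was 4080 in it against 94.4 and 138.1, Dntt 7258 against 0 and 11.01, and Ighm 176989 against 145.1 and 235.2. The WT LT-HSC group includes the library labelled WT LT-HSC replicate 4, without which limma called 72 genes in place of 143 between WT MPP2 and WT LT-HSC. The count was 62 and 49 without WT LT-HSC replicate 2 or 3, and 49, 45 and 284 without WT MPP2 replicate 1, 2 or 3. EdgeR called 35 genes, edgeR on 18 libraries 0, with 1370 at an unadjusted p under 0.05, DESeq2 420 and voom 236. Limma called 364 with the library-number covariate, 260 with sex as a covariate and 266 with a pseudocount of 16. Without WT MPP2 replicate 2 the camera calls of erythroid, cell cycle inhibitor, TNF and NF-kB, interferon, Wnt and BMP and TGF-beta genes were lost. The TNF and NF-kB call was also lost without the library labelled WT LT-HSC replicate 4, and the Wnt call without it, WT LT-HSC replicate 1, WT MPP2 replicate 3 or KO MPP2 replicate 3. The Wnt call was lost with the library-number covariate and without the libraries numbered 52 to 54 as well.

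Between the progenitor types, WT MPP2 had more of several platelet genes than WT MPP3. Pf4, a chemokine stored in platelet granules, was 18222 ± 15479 normalized counts in WT MPP2 (n = 3) against 99.1 ± 53.5 in WT MPP3 (n = 4), a log2 fold change of 6.76 (SE 1.11, limma adjusted p = 0.00894). Cavin2 was 1674 ± 1080 against 4.96 ± 9.92 (log2 9.31, SE 0.94, limma adjusted p = 9.89e-05), and F2r, a thrombin receptor, 3298 ± 1791 against 227 ± 176 (log2 4.13, SE 0.54, limma adjusted p = 0.00116). Flt3 was 1438 ± 2289 in WT MPP2 against 8762 ± 3118 in WT MPP3 (log2 -4.47, SE 0.89, limma adjusted p = 0.0334). That call was lost in 11 of 33 settings, among them edgeR, DESeq2 and 7 fits without a single library. Limma called 74 genes, 44 higher and 30 lower in MPP2.

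The rises held further genes of platelets and their precursors. They were Gp1bb (7.45), Treml1 (6.63), Vwf (6.22), Rab27b, a GTPase of granule release (5.55), Gp5 (5.48) and the thrombin receptor F2rl2 (5.44). Ehd3 (6.28), Slamf1 (5.88) and the tubulin Tuba8 (3.75) rose with them. The falls held the monocarboxylate transporter Slc16a7 (-4.41), Tmem173, which encodes the DNA-sensing adaptor STING (-3.05), Gm17509 (-2.90) and the amino-acid transporter Slc43a2 (-2.67). The lymphocyte kinase gene Lck (-2.54), Akna (-2.26), Fgd2 (-2.22), Pstpip1 (-1.95), Ckap4 (-1.90) and Plppr3 (-1.87) fell as well. Gm15629 (-2.06) is annotated as antisense, and without a stated strand setting its reads cannot be separated from those of a gene on the other strand. All libraries of one type lay beyond all of the other for these 24 genes, whose largest limma adjusted p was 0.045 (Tmem173). The call of Lck was lost in 20 of 33 settings, among them edgeR, voom and 15 fits without a single library. Those of Gm15629, Ckap4, Tmem173, Slc16a7 and Ehd3 were lost in 21, 19, 18, 17 and 16. With the library-number covariate Ehd3, Slamf1, Rab27b, Gp5, Slc16a7, Fgd2, Gm15629, Ckap4 and Plppr3 lost their calls. Mpo (-3.06, limma adjusted p = 0.741), Elane (0.91, limma adjusted p = 0.983) and Gata1 (5.42, limma adjusted p = 0.171) did not pass. Itga2b (2.78, limma adjusted p = 0.123), Procr (-4.97, limma adjusted p = 0.116) and Dntt (-7.63, limma adjusted p = 0.173) did not pass either.

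Megakaryocyte and platelet genes rose in 9 of 20 from WT MPP3 to WT MPP2, or 17 adjusted over the list alone (camera adjusted p = 1.28e-26), with Gp9 at 3.64. TNF and NF-kB response genes were called lower in MPP2 with 0 of 18 passing, or 5 adjusted over the list alone (camera adjusted p = 0.000686). The survival gene Birc3 was at -1.44 and the NF-kB subunit Rel at -1.83. Both lists were called with an estimated correlation too, and the other 12 calls were lost with it. Lymphoid priming genes were called lower with 2 of 18 passing, Flt3 and Lck, or 14 adjusted over the list alone (camera adjusted p = 7.61e-16, estimated-correlation p = 0.0641). Dendritic cell genes were called lower with Flt3 passing among 10, or 4 adjusted over the list alone (camera adjusted p = 1.37e-05, estimated-correlation p = 0.0715). Myeloid genes were called lower with the transcription factor Spi1 (-1.72) passing among 22, or 2 adjusted over the list alone (camera adjusted p = 0.000379, estimated-correlation p = 0.397). Immediate early genes were called lower with 0 of 18 passing, or 1 adjusted over the list alone (camera adjusted p = 0.000379, estimated-correlation p = 0.431). Interferon response genes were called lower with 0 of 22 passing and 0 adjusted over the list alone (camera adjusted p = 0.00176, estimated-correlation p = 0.431).

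HSC markers were called higher in WT MPP2 than in WT MPP3 with Slamf1 and the receptor gene Tek passing among 20, or 6 higher and 1 lower (Procr) adjusted over the list alone (camera adjusted p = 0.00195, estimated-correlation p = 0.38). Erythroid genes were called higher with 0 of 20 passing, or 3 adjusted over the list alone (camera adjusted p = 0.000543, estimated-correlation p = 0.401). Genes of mast cells, basophils and eosinophils were called higher with 0 of 9 passing, or 4 higher and 1 lower (Mcpt8) adjusted over the list alone (camera adjusted p = 0.00379, estimated-correlation p = 0.0618). Mitosis genes were called higher with 0 of 22 passing, or 1 adjusted over the list alone (camera adjusted p = 1.31e-10, estimated-correlation p = 0.377). DNA replication genes were called higher with 0 of 21 passing, or 1 adjusted over the list alone (camera adjusted p = 7.57e-05, estimated-correlation p = 0.397). Histone genes were called higher with 0 of 17 passing, or 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 7.99e-05, estimated-correlation p = 0.377). Nuclear oxidative phosphorylation genes were called higher with 0 of 25 passing, or 1 adjusted over the list alone (camera adjusted p = 0.000359, estimated-correlation p = 0.397).

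WT MPP2 replicate 3, with Flt3 at 4080 and Pf4 at 1374, lay between the types. Limma called 417 genes without it in place of 74 between WT MPP2 and WT MPP3, and 270 without the 3 libraries numbered 52 to 54. The count was 9 and 25 without WT MPP2 replicate 1 or 2, and 48 and 40 without WT MPP3 replicate 1 or 4. It was 49 without KO MPP3 replicate 2 and 124 without KO MPP2 replicate 3, libraries that enter through the shared estimate of spread. EdgeR called 49 genes, edgeR on 18 libraries 12, DESeq2 276 and voom 138. Limma called 119 with a pseudocount of 16 and 0 in a fit of these groups alone. The camera calls of HSC markers and immediate early genes were lost without WT MPP2 replicate 3, the first also without the libraries numbered 52 to 54, those of erythroid and myeloid genes without WT MPP2 replicate 2, and that of DNA replication without WT MPP2 replicate 1. The call of mast cell genes was lost without WT MPP3 replicate 2, and that of interferon genes without it or without WT MPP2 replicate 2.

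**Figure D3:**
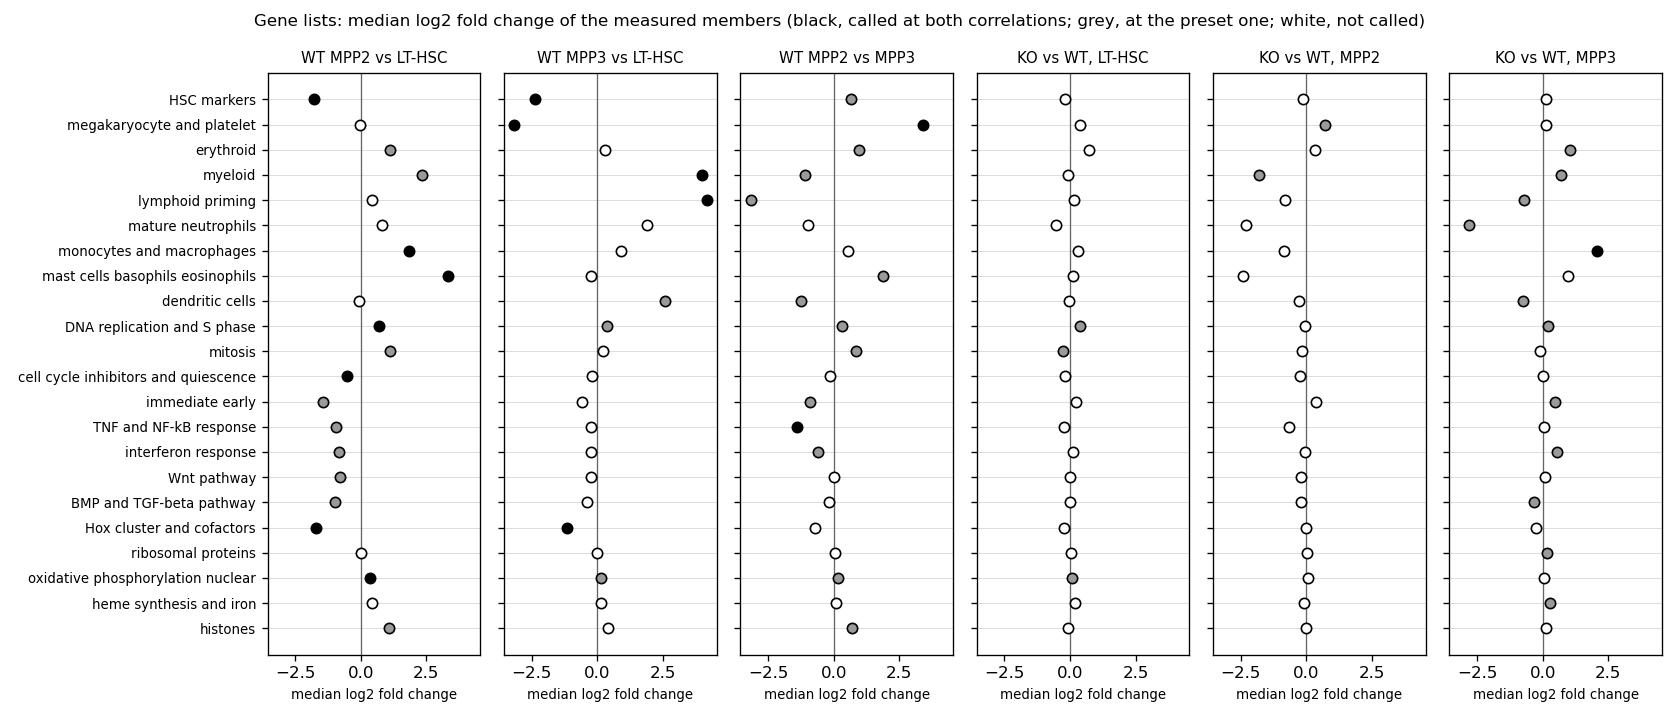
Median log2 fold change over the measured members of 22 gene lists (x axes) in 6 comparisons (panels), for lists called in at least 1 of them; black, called by camera with both correlation settings; grey, with the preset one alone; white, not called. In the knockout panels 1 list, monocytes and macrophages in MPP3, is black.

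The effect of losing Hopx on stem cells was asked by comparing KO with WT LT-HSC. Sva, a gene named for a seminal vesicle antigen, was 107 ± 101 normalized counts in KO LT-HSC (n = 3) and had 0 reads in the 4 WT LT-HSC libraries. It was at least 139-fold higher (limma adjusted p = 0.0147). Sva lies on chromosome 6 at 42038394 to 42042851 on the plus strand (GRCm38) and is protein-coding. It was the only gene whose 9 KO libraries lay beyond all 11 WT libraries. It is below the expression level of the naming rule and was chosen after its values were seen. No other of 17160 genes passed by limma, while 456 had an unadjusted p under 0.05, 151 higher and 305 lower in KO. The balance was nearer even with sex as a covariate (278 of 630 higher) or the library-number covariate (249 of 535). Without KO LT-HSC replicate 3 it was 185 of 803. Among genes that did not pass, those with the smallest p on the positive side were the centromere gene Cenpu (965 ± 142 in KO against 556 ± 134 in WT, log2 0.82), the circadian repressor Cry1 (1.24), Arl6ip6 (0.57), Gpr180 (0.84) and the checkpoint kinase gene Chek1 (0.81). On the negative side they were the zinc-finger gene Zfp35 (551 ± 171 against 1186 ± 213, log2 -1.14), Qrich1 (-0.70), Dnah8 (-1.93), Katnal1 (-1.69) and the ETS factor gene Elf4 (-0.76). All 10 had a limma adjusted p = 1. DNA replication genes were called higher by camera, with a positive fold change in 21 of 21 (median 0.40) and the licensing genes Cdt1 and Mcm4 at 0.64 and 0.43 (camera adjusted p = 7.6e-13). Mitosis genes were called lower, with a negative fold change in 18 of 22 (median -0.25) and the ubiquitin-conjugating gene Ube2c at -1.35 (camera adjusted p = 0.0289). Nuclear oxidative phosphorylation genes were called higher, with a positive fold change in 22 of 25 (median 0.09; camera adjusted p = 0.0148). In each of these lists 0 genes passed over all genes and 0 adjusted over the list alone, and none of the 3 calls was kept with an estimated correlation (adjusted p = 0.393, 0.897 and 0.897).

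KO LT-HSC replicate 1 carried transcripts of B-cell precursors and neutrophils, with Vpreb1 at 733, Igll1 at 1377 and S100a8 at 13782. The WT group includes the library labelled WT LT-HSC replicate 4, whose Hopx was 0. Sva lost its call in LT-HSC without KO LT-HSC replicate 1, KO LT-HSC replicate 3 or WT LT-HSC replicate 3, and without the libraries numbered 52 to 54. It also lost it with voom, edgeR on 20 or 18 libraries, a pseudocount of 16 or a fit of the compared groups alone (adjusted p over all settings 2.40e-06 to 0.962). In these cases 0 genes were called, except 2 with the pseudocount of 16, and 2 were called without WT LT-HSC replicate 1 or 2, the library labelled WT LT-HSC replicate 4 or WT MPP3 replicate 4. Without the library labelled WT LT-HSC replicate 4 the second gene was Hopx. DESeq2 called 21 genes, and limma 3 without the expression filter. The mitosis call was lost without KO LT-HSC replicate 2 or 3, KO MPP2 replicate 3 or WT LT-HSC replicate 1 or 2. The oxidative phosphorylation call was lost without KO LT-HSC replicate 2, WT LT-HSC replicate 3 or the library labelled WT LT-HSC replicate 4, and with the library-number covariate. With sex as a covariate the mitosis call was lost. Without KO LT-HSC replicate 1 or WT LT-HSC replicate 3, 5 lists were called, and without KO LT-HSC replicate 2 there was 1.

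In MPP2, 2 genes passed between KO and WT, and both were chosen for mention after their values were seen. Sva was 77.1 ± 51.9 normalized counts in KO MPP2 (n = 3) and had 0 reads in WT MPP2 (n = 3), at least 77.7-fold higher (limma adjusted p = 0.0499). Eps8l1, a gene of the EPS8 family of actin regulators, lies on chromosome 7 at 4460674 to 4480487 (plus strand, protein-coding). It fell from 65.4 ± 45.3 in WT to 1.502 ± 1.84 in KO (log2 -4.79, SE 0.75, limma adjusted p = 0.0499). An unadjusted p under 0.05 was found for 1353 genes, 250 higher and 1103 lower in KO. The genes of smallest p that did not pass were Mn1, a transcriptional regulator of early progenitors (3.55 ± 6.15 in KO against 85.8 ± 95.5 in WT, log2 -4.68), Tmem50b (-4.51), Zfp467 (-4.97), the nucleoside transporter Slc29a3 (-3.65) and Tnrc18 (-2.87). Each had a limma adjusted p = 0.25. With positive values they were Gm3604 (2.64), Ap3b1, a sorting adaptor of granules (1868 ± 508 against 961 ± 183, log2 0.94), and Eipr1 (0.83), each with a limma adjusted p = 0.257. Nsun4 (1.31) and Rhobtb3 (1.08) followed, with a limma adjusted p = 0.282. Camera called megakaryocyte and platelet genes higher, with a positive fold change in 15 of 20 (median 0.71; camera adjusted p = 0.00899), the platelet selectin Selp at 1.67 and Tubb1 at -2.55. It called myeloid genes lower, with a negative fold change in 18 of 22 (median -1.80; camera adjusted p = 0.0372). Csf3r, the receptor of granulocyte colony-stimulating factor, was at -3.19 and Clec12a at -4.90. In both lists 0 genes passed over all genes and 0 adjusted over the list alone, and both calls were lost with an estimated correlation (adjusted p = 0.952 each). Some lists of other blood cells, not called, leaned the same way as the myeloid one, while the erythroid list, not called either, did not (median 0.33). Fold changes were negative in 9 of 12 mature neutrophil genes (median -2.32; camera adjusted p = 0.136), 7 of 9 genes of mast cells, basophils and eosinophils (median -2.43; camera adjusted p = 0.261) and 14 of 18 lymphoid priming genes (median -0.83; camera adjusted p = 0.0722). In each of these 3 lists 1 gene was lower when adjusted over the list alone.

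Fewer genes were read in KO MPP2 replicate 3 (14931) and KO MPP2 replicate 1 (16220) than in the WT MPP2 libraries (17021 to 18469). Elane was 14769 in WT MPP2 replicate 3 against 6105 and 2.001 in the other WT MPP2 libraries. Without KO MPP2 replicate 2 limma called 350 genes, 16 higher and 334 lower in KO MPP2. It called 1 without KO LT-HSC replicate 1. It called 0 without any 1 of KO LT-HSC replicate 3, KO MPP2 replicate 3, the 3 KO MPP3, 4 WT LT-HSC and 3 WT MPP2 libraries or WT MPP3 replicates 1, 2 and 4. With 1 library left out at a time, Sva lost its call in MPP2 in 15 of 20 fits and Eps8l1 in 17. No gene was called by edgeR (1136 at an unadjusted p under 0.05) or voom (336), or by limma with TMM scaling, a pseudocount of 16, no filter, the sex or library-number covariate, a fit of the compared groups alone or without the libraries numbered 52 to 54. DESeq2 called 112, 20 higher and 92 lower. Both list calls in KO MPP2 were lost without KO MPP2 replicate 1 or 2, WT MPP2 replicate 3 or the 3 libraries numbered 52 to 54, and the myeloid one without WT MPP2 replicate 1. The lists called numbered 0, 0 and 5 without KO MPP2 replicate 1, 2 or 3, and 5, 8 and 1 without WT MPP2 replicate 1, 2 or 3.

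In MPP3, Sva was again the gene that passed between KO and WT, chosen for mention after its values were seen. It was 74.6 ± 45.5 normalized counts in KO MPP3 (n = 3) against 0.314 ± 0.628 in WT MPP3 (n = 4), with a log2 fold change of 5.69 (SE 0.84, limma adjusted p = 0.0468). Its 239 reads against 1 gave a ratio of 309 (counting interval 54.9 to 12238). An unadjusted p under 0.05 was found for 347 genes, 195 higher and 152 lower in KO. This balance was not stable: 108 of 328 were higher without WT MPP3 replicate 3, and 308 of 435 without the libraries numbered 52 to 54. The genes of smallest p that did not pass were the proteoglycan Sdc2 (119 ± 108 in KO against 14.4 ± 26.5 in WT, log2 4.55), Gp9 (162 ± 57.2 against 67.8 ± 14.2, log2 1.20), Commd10 (0.76), Siva1 (0.48) and Abcb8 (0.69) with positive values. With negative values they included Gatad2b (-0.62), Med12l (-1.23), Fan1, a nuclease of crosslink repair (-1.63), and Rpl34-ps1 (-1.06). Rpl34-ps1 is a processed pseudogene whose reads may belong to its parent gene. Each of these genes had a limma adjusted p = 1.

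Monocyte and macrophage genes were called higher in KO MPP3 with either correlation setting (camera adjusted p = 0.000558, and adjusted p = 0.0483 with an estimated correlation), though not by fry (adjusted p = 0.171). The fold change was positive in 9 of 12 (median 2.08), with Adgre1, the gene of the F4/80 antigen, at 4.07 and the complement genes C1qb and C1qc at 4.95 and 3.15. C1qb was 278, 17.9 and 93.6 in the KO MPP3 libraries and 42.7 in WT MPP3 replicate 2 but 0 in the other WT MPP3 libraries. Camera called 11 further lists. In each of the 12, 0 genes passed over all genes and 0 adjusted over the list alone. Erythroid genes were called higher (18 of 20 positive, camera adjusted p = 4.2e-05), with the red-cell factors Gata1 at 3.86 and Klf1 at 4.10. Myeloid genes were called higher (18 of 22, camera adjusted p = 0.00592), with Elane at 4.77, as were interferon response genes (19 of 22, camera adjusted p = 0.000171), with Ifit1 at 3.09. Ribosomal protein genes were called higher (27 of 28, median 0.17, camera adjusted p = 9.87e-06), with Rplp0 at 0.24. DNA replication (16 of 21 positive, camera adjusted p = 0.00969), immediate early (16 of 18, 0.0154) and heme synthesis and iron genes (13 of 15, 0.0031) were called higher too. Lymphoid priming genes were called lower (18 of 18 negative, median -0.70, camera adjusted p = 7.01e-05), with Il7r at -3.26. Rag1 had 58 reads in WT MPP3 and 0 in KO MPP3, at least 14.97-fold lower. Mature neutrophil genes were called lower (11 of 12, camera adjusted p = 0.000399), with Ltf at -3.10, as were dendritic cell genes (8 of 10, 0.0244) and the BMP and TGF-beta pathway (16 of 21, 0.0405). These 11 calls were lost with an estimated correlation, with an adjusted p = 0.624 for DNA replication, 0.673 for immediate early, 0.532 for myeloid and 0.521 for each of the others.

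The WT MPP3 libraries were uneven in the same groups. Gata1 was 1256 and 634 in replicates 1 and 4 but 12.6 and 0 in replicates 2 and 3, and Elane was 9331 and 8221 but 2.51 and 51.7. The neutrophil genes S100a8 and Ltf were 10521 and 2552 in WT MPP3 replicate 2. Sva lost its call in MPP3 in 23 of 33 settings (adjusted p 0.000276 to 1). Among them were edgeR, voom, the sex and library-number covariates, a pseudocount of 16, a fit of the compared groups alone, the fit without the libraries numbered 52 to 54, and 15 fits without a single library. Limma called 2 genes without WT MPP3 replicate 2 (Sva and Sdc2) or the library labelled WT LT-HSC replicate 4 (Sva and Hopx), and 0 without any other library except KO LT-HSC replicate 1 or 2 or KO MPP2 replicate 1. DESeq2 called 22, and limma 3 without the expression filter. Without WT MPP3 replicate 2 the number of lists was 7, and myeloid, mature neutrophil and 5 other calls were lost. The others were dendritic cells, DNA replication, immediate early, BMP and TGF-beta, and heme synthesis, and the immediate early list took the opposite direction. Without the libraries numbered 52 to 54 the same 7 calls were lost, with the immediate early list again in the opposite direction. With the library-number covariate 6 of the 12 calls were kept, and those of lymphoid priming, dendritic cells, DNA replication, immediate early, BMP and TGF-beta and heme synthesis were lost. It was 6 without KO MPP3 replicate 1, where the erythroid, interferon, DNA replication, immediate early, BMP and TGF-beta and heme synthesis calls were lost. The last 4 of these were lost without KO MPP3 replicate 2 as well, and the BMP and TGF-beta call without WT MPP3 replicate 3 or 4. The monocyte and macrophage and dendritic cell calls were lost without KO MPP3 replicate 3.

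On average over the 3 populations, Sva rose and Hopx fell, and no other gene passed. Libraries of different populations may share an animal, which the fit does not model, so the SE and p of both averages may be too small. Sva had a log2 fold change of 5.94 (SE 0.50, limma adjusted p = 1.10e-05) and lost its call with edgeR on 18 libraries alone (edgeR adjusted p = 0.0863). It had 802 reads in 9 of 9 KO libraries and 1 read in 1 of 11 WT libraries, which gave a ratio of 950 (counting interval 170 to 37586). An unadjusted p under 0.05 was found for 864 genes, 271 higher and 593 lower in KO. The balance was nearer even with sex as a covariate (648 of 1318 higher) or the library-number covariate (330 of 738). Without KO MPP2 replicate 2 it was 348 of 1589. Camera called 9 lists on the average, each with 0 genes passing over all genes. Called higher were megakaryocyte and platelet genes (16 of 20 positive, camera adjusted p = 0.000892), with Gp9 at 0.62, erythroid genes (15 of 20, 0.000245), DNA replication (21 of 21, median 0.20, 1.25e-06), immediate early genes (17 of 18, 0.000892), interferon response (16 of 22, 0.00134), with the ubiquitin-like Isg15 at 0.66, ribosomal proteins (23 of 28, median 0.08, 3.95e-05) and nuclear oxidative phosphorylation (21 of 25, median 0.08, 0.00134). Called lower were lymphoid priming (15 of 18 negative, camera adjusted p = 0.00686), in which Mn1 (-1.83) passed when adjusted over the list alone, and mature neutrophils (12 of 12, 0.00399), with Ngp, a neutrophil granule protein, at -3.95 and a value of 4482 in WT MPP3 replicate 2. In the other 8 lists 0 genes passed adjusted over the list alone. None of the 9 calls was kept with an estimated correlation, with an adjusted p = 0.701 for lymphoid priming, 0.672 for mature neutrophils and 0.648 for the others. The test of whether the KO effect differed between populations called 0 genes by limma (526 at an unadjusted p under 0.05), 0 by edgeR and voom and 8 by DESeq2. Without KO MPP2 replicate 2 the average gave 72 genes and the test of the difference 83; DESeq2 called 54 genes on the average and edgeR 1. Without the libraries numbered 52 to 54 the average calls of megakaryocyte, lymphoid, DNA replication, immediate early and oxidative phosphorylation genes were lost, and lymphoid priming and immediate early genes took the opposite sign. With the library-number covariate 3 of the 9 calls were kept, those of megakaryocyte, lymphoid, neutrophil, DNA replication, immediate early and oxidative phosphorylation genes were lost, and lymphoid priming and immediate early genes again took the opposite sign. The interferon call was lost with sex as a covariate. Leaving out 1 library, the megakaryocyte call was lost without WT MPP2 replicate 3 and the lymphoid one without it, KO LT-HSC replicate 3 or KO MPP2 replicate 1. The neutrophil call was lost without KO MPP2 replicate 2, WT LT-HSC replicate 2 or WT MPP2 replicate 2, and the interferon call without WT MPP2 replicate 2.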

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

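Several tests were chosen only after the result was seen. They were those of Sva in the library labelled WT LT-HSC replicate 4 and against sex, library number and neighbouring genes. The others were those of B lineage genes and of the total reads of KO MPP2. The use of left-out WT MPP3 and WT MPP2 libraries as ranges was also chosen then. Among 204 sets of values from 4 libraries, over 101 named genes and the read and gene totals, 13 held 1 library far from the others on the log2 scale. The cutoff is meant to give about 1 in 20 by chance for normally spread values, which was not tested on these data. The 13 of 204 sets are near that share, so a flag alone does not show that a library is unusual. A set in which all libraries but 1 are at 0 always exceeds the cutoff. This was so for Dntt, Atp8b4, Ly6c2, Cavin2 and Sva below.

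Hopx was 0 in the library labelled WT LT-HSC replicate 4, while the others ran from 30.2 to 58.9. Of 1021 genes of like mean level in those libraries, 36 were also at 0 in it (3.53%, against a median of 5.84% in the other libraries). These genes were matched on their mean and not on their spread, so the share cannot decide how unusual the 0 is for Hopx. Sva was at 19.1 or more in each KO library and had 0 reads in the library labelled WT LT-HSC replicate 4. Sva was picked with that library counted as WT, so this value cannot test whether the label is right. In WT LT-HSC replicate 3, the integrin gene Itga2b was 751 (others 3548 to 4814), the platelet gene Gp1bb 28.6 (1030 to 1848), Plac8 3109 (761 to 902) and Dntt 23.3 (others 0). In WT LT-HSC replicate 2, Atp8b4 was 37.0 and Ly6c2 46.5 (others 0), and Ckap4 was 416 (263 to 279). Slc29a3 was 114 in WT LT-HSC replicate 1 (266 to 313). Among WT MPP3 libraries, Itga2b was 1824 in replicate 3 (297 to 393), where the growth suppressor Ndn was 0 (36.3 to 42.4), Cavin2 was 19.8 in replicate 4 (others 0), and Sva was 1.26 in replicate 2 (others 0).

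Sva was read in all 9 KO libraries and, with 1 read, in 1 WT library. The reads did not follow sex: the lowest value in a male KO library was 81.7 and the highest in a female WT library 1.26. Nor did they follow the library-number block. In the 3 blocks with both genotypes, 0 of 8 WT libraries and 9 of 9 KO libraries held Sva reads. Sva was picked by its difference between KO and WT, which favours such a separation. These values therefore describe Sva and are no independent evidence for an effect of genotype. Sva lies on chromosome 6 and Hopx on chromosome 5, so a strain haplotype around Sva would not be carried with the knockout allele by linkage. A haplotype that differs between the KO and WT animals for another reason stays open: 0 of 60 other tested genes within 5 Mb were called on average, but a haplotype need not change expression, so it cannot be told apart from an effect of losing Hopx. Regulation of Sva by Hopx may also explain the reads and was not tested.

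The WT libraries numbered 52 to 54 (WT MPP3 replicate 2, WT MPP2 replicate 3 and WT LT-HSC replicate 3) shared residuals, with a correlation across genes of 0.288 to 0.318 in 3 pairs, against -0.252 to 0.198 in 125 pairs from different blocks. They are the WT female libraries, and the block cannot be told apart from sex. The labels name no animal, so an animal shared by these libraries cannot be told apart from block or sex either. Their difference from other WT libraries correlated at -0.228 over 16397 autosomal genes with the female minus male difference in KO. The bound set before on that value was wrong, since all 3 male KO libraries are in block 115 to 120 and 0 of 3 KO blocks held both sexes. The bounds set before did not decide whether WT MPP2 replicate 3 is an MPP3 library. Over 478 genes its median position between WT MPP3 at 0 and the other WT MPP2 at 1 was 0.389, between those bounds. This lay beyond left-out WT MPP3 libraries (-0.0813 to 0.0749). It also lay below WT MPP2 replicates 1 and 2, each set against the other (0.899 to 1), so it was outside both ranges. A mixture of both cell types may give such a position and was not tested. Mature B lineage cells cannot be told apart from other sources of its Ighm (176989), since 6 of 12 B lineage genes exceeded 10 normalized counts, with Cd79b at 913 and Cd79a at 287 but Pax5 and Cd22 at 0, and sorting against lineage antigens would remove most such cells.

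Without KO MPP2 replicate 2, 334 genes were lower and 16 higher in KO MPP2. Fewer reads are argued against, since KO MPP2 libraries, replicate 2 included, held on average 105% of the gene reads of WT MPP2. KO MPP2 replicates 1 and 3 held 13933069 and 14255558 gene reads, within the WT MPP2 range of 13035794 to 15153309. Of the 334 genes, 96 had 0 reads in KO MPP2 replicate 1, 149 in replicate 3 and 1 in replicate 2, and the medians against WT MPP2 were -3.86, -5.16 and -0.27 on the log2 scale. Low gene detection in replicates 1 and 3 cannot be told apart from biology: in WT MPP3 replicate 3, the WT library with the fewest genes read, these genes lay a median of -0.11 from the other WT MPP3 libraries, while 1000 matched lists gave -0.345 to 0.103. An effect of losing Hopx that is weak in KO MPP2 replicate 2 stays open as well, untested.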

How the results depend on the processing

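The edgeR test had been set as the main test before the data were examined and became an alternative once the unit of the values was known. It called 0 genes in each single-population knockout comparison, where limma called 1, 2 and 1. EdgeR on 18 libraries, TMM scaling, other pseudocounts, the sex covariate and leaving out libraries 52 to 54 were chosen after the data were seen. The labels name no animal and give the groups no shared replicate numbers, so libraries were not paired by animal. The library numbers fall into 4 blocks, which were fitted as a covariate. Deviations of libraries of one genotype in one block correlated across genes at 0.288 to 0.318 for WT 52 to 54 and 0.115 to 0.187 for KO 115 to 120. The values were 0.0347 to 0.173 for WT 115 to 120 and 0.140 for WT 101 to 106. They were lower for WT 81 to 88 (0.0245 to 0.0898), KO 101 to 106 (0.0182 to 0.0643) and KO 81 to 88 (0.00783). Since they were uneven, the blocks were not taken as pairs. No named gene reversed its sign under any setting run. For genes named between WT populations, 746 of 934 checks over settings and 1179 of 1440 with 1 library left out kept the call or its absence, and the others lost it (188 and 261). For genes named in the knockout comparisons, 453 of 505 checks over settings and 719 of 780 with 1 library left out did so. A further 41 and 50 lost a call, and 11 in each case gained one. DESeq2 gave no adjusted p for 2 named genes, which were left out there. A fit of the compared groups alone does not exist for the average and for the test of the difference, and was not run there. Median-ratio scaling and a pseudocount of 0.5 moved no count of genes by over 1.5 times, and the lists were not tested with them.

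For KO LT-HSC, limma's 1 gene became 3 with no expression filter, 21 with DESeq2, 2 with a pseudocount of 16, and 0 with voom, the compared groups alone, edgeR, edgeR on 18 libraries or without libraries 52 to 54. In KO MPP2, 2 genes became 112 with DESeq2 and 0 with no filter, voom, the compared groups alone, the library-number covariate, edgeR, edgeR on 18 libraries, TMM, a pseudocount of 16, the sex covariate or without libraries 52 to 54. In KO MPP3, 1 gene became 3 with no filter, 22 with DESeq2, and 0 with voom, the compared groups alone, the library-number or sex covariate, edgeR, edgeR on 18 libraries, a pseudocount of 16 or without libraries 52 to 54. Genes at an unadjusted p under 0.05 by edgeR numbered 434, 1136 and 314 in the 3 populations, and by voom 816, 336 and 727. On average, 2 genes became 54 with DESeq2, 1 with voom, the library-number covariate, edgeR, a pseudocount of 16 or without libraries 52 to 54, and 0 with edgeR on 18 libraries. The test of the difference went from 0 to 8 with DESeq2.

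Between WT MPP2 and WT LT-HSC, 143 genes became 420 with DESeq2, 236 with voom, 364 with the library-number covariate, 35 with edgeR, 0 with edgeR on 18 libraries (1370 at an unadjusted p under 0.05), 266 with a pseudocount of 16 and 260 with the sex covariate. Between WT MPP3 and WT LT-HSC, 681 became 1608 with voom, 429 with edgeR and 242 with edgeR on 18 libraries. Between WT MPP2 and WT MPP3, 74 became 276 with DESeq2, 138 with voom, 0 with the compared groups alone, 49 with edgeR, 12 with edgeR on 18 libraries, 119 with a pseudocount of 16 and 270 without libraries 52 to 54. The 18-library fit has fewer libraries and lacks WT MPP3 replicate 1 and WT MPP2 replicate 2. The cause of its moves and of the others was not tested.

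Lists called in KO LT-HSC went from 3 to 0 with an estimated correlation, with fry and with fry's mixed test, 5 with the library-number covariate and 8 without libraries 52 to 54. In KO MPP2, 2 became 0 with the estimated correlation and both fry tests, and 5 with the library-number or sex covariate. In KO MPP3, 12 became 1 with the estimated correlation, 0 with both fry tests and 7 without libraries 52 to 54. On average, 9 became 0 with the estimated correlation and both fry tests, and 5 with the library-number covariate. Between WT MPP2 and WT LT-HSC 16 became 7 with the estimated correlation, between WT MPP3 and WT LT-HSC 8 became 5, and 22 with fry's mixed test, and between WT MPP2 and WT MPP3 14 became 2, and 5 with fry. Fry does not compare a list with other genes.

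Leaving out 1 library at a time, called genes ranged from 0 to 2 in KO LT-HSC, 0 to 350 in KO MPP2, 0 to 2 in KO MPP3, 2 to 72 on average and 0 to 83 for the test of the difference, where 350, 72 and 83 came without KO MPP2 replicate 2. They ranged from 45 (without WT MPP2 replicate 2) to 284 (without WT MPP2 replicate 3) between WT MPP2 and WT LT-HSC, 444 (without the library labelled WT LT-HSC replicate 4) to 839 between WT MPP3 and WT LT-HSC, and 9 (without WT MPP2 replicate 1) to 417 (without WT MPP2 replicate 3) between WT MPP2 and WT MPP3. Called lists ranged from 1 to 5, 0 to 8 and 6 to 16 in KO LT-HSC, MPP2 and MPP3, 8 to 11 on average, and 12 to 21, 8 to 12 and 12 to 16 in the WT comparisons in the same order. With every single library left out, 1 of 3 list calls in KO LT-HSC (DNA replication), 0 of 2 in KO MPP2, 2 of 12 in KO MPP3 (lymphoid priming and ribosomal proteins) and 5 of 9 on average were found each time. In the WT comparisons this held for 10 of 16, 8 of 8 and 7 of 14 list calls. With the library-number covariate, 2 of 3, 2 of 2, 6 of 12 and 3 of 9 list calls were found again in KO LT-HSC, MPP2, MPP3 and on average, and 15 of 16, 8 of 8 and 14 of 14 in the WT comparisons.

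Depth limits genes with few reads, such as Hopx with 104 to 130 reads per WT population, and a value of 0 there does not exclude transcripts below the floor of 3 counts.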

Other observations

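The differences between populations were found in KO libraries too, a test set before its result was seen; the KO list tests and the KO genes named here were chosen after. In KO MPP3 against KO LT-HSC, Cavin2 (log2 -10.93), Slamf1 (-6.86), Vwf (-5.49) and Pf4 (-7.33) were lower, and Mpo (12.98) and Flt3 (4.96) higher, as in WT, with limma adjusted p of 0.00232 for Slamf1, 0.00372 for Mpo and 0.00887 for Flt3. KO MPP2 had less Procr than KO LT-HSC (log2 -7.89, limma adjusted p = 0.0111), and more Cavin2 (10.72), Pf4 (8.69) and Slamf1 (6.18) and less Flt3 (-4.60) and Dntt (-9.79) than KO MPP3. Of the genes called in WT, 99.3% (142 of 143) had the same sign in KO between MPP2 and LT-HSC, 98.8% (673 of 681) between MPP3 and LT-HSC, and 100% (74 of 74) between MPP2 and MPP3, against 67.7, 66.6 and 64.7% of all genes tested. In KO, limma called 206, 327 and 478 genes, of which 47, 258 and 58 were also called in WT, all with the same sign, where independent calls would share 1.72, 12.98 and 2.06.

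Some list calls recurred in KO. Of 8 lists called between WT MPP3 and WT LT-HSC, 7 were called in the same direction in KO, among them HSC markers, megakaryocyte, myeloid and Hox genes, which were also called there with an estimated correlation (camera adjusted p = 0.00747, 0.00776, 0.00776 and 0.0429), as were monocyte and macrophage genes (0.0150), a list not called in WT. Of 16 and 14 lists called for WT MPP2 against LT-HSC and MPP3, 10 and 9 were called in the same direction in KO, and 0 in the opposite one; with an estimated correlation KO gave 0 and 1 (megakaryocyte genes, 0.0255). The p53 list was called lower in KO MPP2 than in KO LT-HSC (camera adjusted p = 0.0439; estimated-correlation adjusted p = 0.124).

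Of 35 lists, 13 were called in none of the 7 comparisons, with a smallest camera adjusted p of 0.283 for B lineage cells, 0.141 for T and NK cells, 0.125 for stroma and endothelium, 0.112 for antigen presentation, 0.456 for SRF targets, 0.267 for CXCL12, CXCR4 and adhesion, and 0.206 for the mitochondrial genome. For glycolysis it was 0.128, for cholesterol synthesis 0.2499, for p53 0.266, for heat shock and the unfolded protein response 0.128, for apoptosis and survival 0.377, and for sex-linked genes 0.128. Camera detected no difference in these lists in those 7 comparisons, which does not show that none exists. The sex-linked list, though not called, had a median log2 fold change of -3.89, -2.91 and -3.76 in KO LT-HSC, MPP2 and MPP3. Each KO group held 2 female libraries against 1 in each WT group, so these groups are not balanced for sex.

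Exchanging libraries between groups gave at least as many genes in 17 of 35 splits for KO LT-HSC (real 1, highest other 9), 8 of 35 for KO MPP3 (1 and 4) and 8 of 100 drawn splits for the average (2 and 9), so chance is not excluded for these counts. The test of the difference called 0 genes by limma (526 at an unadjusted p under 0.05), 0 by edgeR (549), 0 by voom (557) and 8 by DESeq2. With a real count of 0, all 100 of 100 splits must reach it (highest other 19), so the splits decide nothing there. For KO MPP2 the 10 splits are too few for a share under 0.05. The real count was 2 and the highest other 88, in a split exchanging WT MPP2 replicate 1 with KO MPP2 replicate 2. That split crosses genotype and sets the MPP2 libraries with the fewest genes read (14931, 16220 and 17021) against those with 18161 to 18469. This points to a structure among these libraries that crosses genotype. The split also parts the library-number blocks, with 81 to 88 and 101 to 106 against 52 to 54 and 115 to 120. Genes read and block therefore cannot be told apart in it. No other split reached the real count for WT MPP2 against LT-HSC (1 of 35 splits, 143 genes, highest other 40) or WT MPP3 against LT-HSC (1 of 35, 681, highest other 7). These counts argue against chance, but 1 of 35 is the smallest share possible and the splits ignore shared blocks or animals. For WT MPP2 against MPP3 the splits alone did not exclude chance (2 of 35, 74 genes), since exchanging WT MPP2 replicate 3 with WT MPP3 replicate 3 gave 81. In the KO libraries 74 of these 74 genes kept their sign, against 64.7% of all genes. Limma called 58 of them there, where independent calls would share 2.06, though both calls use a shared estimate of spread. These values argue against chance for the 74 genes.

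Principal components held 20.2, 15.8 and 8.93% of the variance. WT MPP2 replicate 3 had 5.84% of its gene reads on the mitochondrial genome and 10.02% in its 10 most abundant genes. The 3 annotated genes within 100 kb of Sva reached at most 0.874 in any library, and 0 of 55 tested genes within 5 Mb of Hopx were called on average.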
